A study of Mus musculus with 12 samples.

How the data were processed

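RNA was measured on 12 Illumina mouse bead arrays, 3 in each of 4 groups: fresh liver and freshly isolated hepatocytes of IkkβF/F mice (FF) and of IkkβΔhep mice (Dhep). Per the labels' protocols, RNA was extracted with guanidine thiocyanate, cleaned up with DNase I treatment on columns, and checked by gel electrophoresis and on a Bioanalyser. Biotinylated cRNA was prepared with an Illumina TotalPrep amplification kit, per the labels' protocols. BeadStudio was named by the submitters without a version, and its background setting is not given in the sources used here.

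The deposited raw table holds the authors' linear bead intensity per probe, without normalization between arrays. A second deposited table holds the authors' intensity after a normalization whose method is not given in the sources used here. In the raw table the median intensity per array ran from 41.0 to 53.8, and in the normalized table from 47.1 to 47.3. Pearson's r across probes between an array's raw and normalized values was 0.998 to 1.00, and all 12 columns matched their own array best. The raw table carried no detection p, so the background correction planned first (neqc) could not be run, and normexp without negative controls was used. The raw intensities were corrected with normexp (offset 50), taken to log2 and quantile normalized in limma 3.58.1 under R 4.3.3. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

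Of 45281 probes, 34885 carried 1 gene symbol, 18 several and 10378 none. Probes were kept when they exceeded the median of all probe means, 6.06 on the log2 scale or 66.7 in linear units, on every array of at least 1 group. This kept 22859 probes (50.5%), of which 19222 had a symbol, for 12010 genes. A difference against a group at that floor on all its arrays, or in its mean, is given as at least the distance to the floor. The number of arrays limits the precision, and so does the number of mice.

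The study's description gives 4 mice and 4 RNA samples. The 3 arrays of a group were therefore taken as repeat arrays of 1 RNA sample from 1 mouse, and p-values between arrays compare RNA samples rather than genotypes or preparations in general. Replicate numbers in the titles were not taken to pair arrays across groups. The labels state an age of 4 to 6 weeks and the study's description 6 to 8 weeks.

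A linear model with 4 group means was fitted to all 12 arrays with limma's lmFit and eBayes (8 residual degrees of freedom, 14.8 from the prior). From it came the genotype difference (Dhep minus FF) in liver and in isolated hepatocytes, the isolation difference (hepatocytes minus liver) in FF and in Dhep, and the difference between the genotype differences. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 over all 22859 probes and an absolute log2 difference of at least 1. A second model, preparation plus genotype, was fitted to the 4 RNA means, with 1 residual degree of freedom and 2.33 from the prior. Standard errors (SE) are from limma, and standard deviations (SD) are between the 3 arrays of a group.

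Gene groups were 31 gene lists and 10 lists of cell type markers. Each gene was represented by its kept probe of highest mean signal. The lists name 976 genes, of which 786 were measured. Lists were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 41 lists of a contrast, and with fry. Genes were named by a rule: for each genotype contrast, and for isolation in both genotypes together, up to 8 of the largest called differences each way with no overlap between the arrays. The rule added up to 4 members with the largest difference from each list described, Ikbkb, Chuk, Ikbkg and Alb, and the 5 largest called interaction probes each way. Chuk matched no symbol of the arrays and was not analysed here. Gene neighbourhoods followed RefSeq genes on GRCm38.p6.

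Groups, comparisons, tests of probes and lists, the lists, the naming rule and all alternatives but 1 were set before the data were examined. The background correction was not, nor were some tests of explanations, which are named where they are given. Alternatives were no background correction, the authors' normalized table, median scaling or cyclic loess in place of quantile normalization, no filter or a filter on all arrays, a trended robust prior, the replicate number as a block, only the groups compared, no fold threshold, limma's treat against a fold of 1.5, and leaving out each array. The RNA means were set against all arrays with the RNA sample as a random block (duplicateCorrelation, statmod 1.5.0). An offset of 16 was added after seeing the data.

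The fits were tested on simulated data with 50 changed probes per fold among 22859. At folds of 3 and 4, all 50 probes were called in each of the 5 array contrasts, with 0 false calls. For these contrasts the simulated noise was independent and of the size seen between repeat arrays, without spread between mice. False calls at the fold threshold were thus unlikely in advance, and their absence says nothing about differences between mice. At a fold of 2, which sits on the threshold, 23 of 50 were called for genotype in liver, 23 for genotype in hepatocytes, 24 for isolation in FF, 33 for isolation in Dhep and 29 for the interaction. In the fit over 4 RNA means, all 50 probes were called at a fold of 3, with 9 false calls. The simulated spread between RNA samples was that fit's own variance after shrinkage by eBayes. On the real data that fit called 0 probes for genotype, although 172 had an absolute log2 difference of at least 1. The simulation therefore does not show what that fit could call in the real data. For genotype in liver, camera found all 3 lists shifted by 0.25 on the log2 scale and 0 of 27 untouched lists among 41. Genes varied independently in that simulation, so it does not check camera where list members are correlated.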

Results

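RNA levels across the genome were measured on 12 Illumina mouse bead arrays, 3 for each of 4 groups of male mice. Liver tissue and hepatocytes freshly isolated from liver were compared in IkkβF/F mice (FF, Cre-negative) and IkkβΔhep mice (Dhep, Cre-positive, in which Ikkβ is deleted in hepatocytes). Ikkβ, encoded by Ikbkb, is a kinase that activates the transcription factor NF-κB. The 3 arrays of a group were taken as repeat arrays of 1 RNA sample from 1 mouse, since the study's description gives 4 mice and 4 RNA samples. Median raw intensity per array ran from 41.0 to 53.8 and the 75th percentile from 75.5 to 119. The 3 FF hepatocyte arrays had the lowest 75th percentiles, up to 85.7, and the other arrays stood at 94.7 or more. After normalization, Pearson's r across probes was 0.998 within groups and 0.974 to 0.992 between arrays of different groups. The median SD between the 3 arrays of a group was 0.059 to 0.067 on the log2 scale.

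Ikbkb itself was not called different in any comparison. Its kept probe (ILMN_2589556) had a mean log2 signal of 7.62 ± 0.07 in FF liver and 7.47 ± 0.10 in Dhep liver (SD, n = 3 arrays). In hepatocytes the means were 7.35 ± 0.06 in FF and 7.66 ± 0.03 in Dhep (SD, n = 3 arrays). The other 2 Ikbkb probes had means below the floor in all 4 groups, and the position of the kept probe relative to the deleted segment was not analysed here, so these values do not check the deletion. Ikbkg, the regulatory subunit of the same kinase complex, had log2 means of 9.22 in FF liver, 8.96 in Dhep liver, 8.75 in FF hepatocytes and 9.23 in Dhep hepatocytes on its brightest probe (ILMN_2598585). Its other 2 kept probes stood at 7.50 in FF and 7.56 in Dhep hepatocytes and at 6.01 and 6.10. None of the 16 measured genes of the IKK and NF-κB pathway list was called for genotype in either preparation. The list's median was -0.03 in liver (camera adjusted p = 0.944) and 0.22 in hepatocytes (0.0134, and adjusted p = 0.133 with an estimated correlation).

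The first comparison asked how liver RNA labelled Dhep differed from liver RNA labelled FF. The largest increases were in genes of MHC class II antigen presentation. Cd74, the invariant chain that escorts class II molecules, was 8.04-fold higher in Dhep liver (log2 difference 3.01 ± 0.05, SE, n = 3 arrays per group, limma adjusted p = 5.47e-22). H2-Ab1, a class II chain, was 8.18-fold higher (3.03 ± 0.06), and Cxcl9, a chemokine induced by interferon-γ, was 4.47-fold higher (2.16 ± 0.05). Nat8, an N-acetyltransferase gene, was 2.89-fold lower (-1.53 ± 0.05). In all, 115 probes were higher and 21 lower in Dhep liver, representing 68 and 13 named genes. Without the fold threshold 2990 were higher and 3361 lower, so the excess of rises lay in the larger differences.

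Of 14 measured MHC class II and antigen presentation genes, 8 rose, 0 fell and 6 did not pass in Dhep liver, with a median of 1.08 (adjusted p = 0.000104 with an estimated correlation). This list, called the MHC class II list or median below, also holds the class I genes B2m, H2-D1 and H2-K1. H2-Eb1 (2.94), H2-Aa (2.55) and the peptide-loading gene H2-DMa (2.09) rose with Cd74. Of 24 markers of Kupffer cells and macrophages, 12 rose and 0 fell, with a median of 0.97 (adjusted p = 7.02e-05 with an estimated correlation). They included the scavenger receptor Marco (1.79), the complement genes C1qc (1.54) and C1qb (1.43), and Aif1 (1.45, and 0.52 on the lowest of its 3 probes). Of 29 interferon-stimulated genes, 7 rose and 0 fell, with a median of 0.28 (0.00149 by the same test). Igtp, an interferon-inducible GTPase, rose by 1.79, and the immunoproteasome subunits Psmb8 and Psmb9 rose by 1.76 and 1.69. The interferon-inducible GTPase Gvin1 (2.00) and the trefoil factor Tff3 (1.92) also rose.

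Inflammatory gene lists also had higher medians in Dhep liver. Among 27 NF-κB target genes, 2 rose and 0 fell (median 0.17, adjusted p = 0.00306 with an estimated correlation): the siderophore-binding protein Lcn2 (1.89) and serum amyloid Saa3 (1.70). Cxcl10 (0.95) and Vcam1 (0.92) did not pass the fold threshold, although both passed with cyclic loess (1.02 and 1.00) and Cxcl10 also without Dhep liver array 1 (1.00). Of 25 acute phase genes, 3 rose and 0 fell (median 0.21, 0.00831), the third being Socs3 (1.48), a feedback inhibitor of cytokine signalling, on a probe high in Dhep liver alone. Of 11 neutrophil markers, 3 rose (median 0.18, 0.00831), namely Lcn2, Fpr2 (1.27) and S100a8 (1.13). Of 16 T and NK cell markers, 1 rose, the chemokine Ccl5 (1.49), also high in Dhep liver alone, with a median of 0.17 (0.0272). None of 34 cell cycle genes passed singly, although the list's median was 0.15 (0.00792).

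Genes of PPARα targets and fatty acid oxidation moved the other way, with 0 of 26 higher, 1 lower and a median of -0.24 in Dhep liver (adjusted p = 0.0172 with an estimated correlation). The fatty acid hydroxylase Cyp4a14 fell (-1.02), and Acot1 stood at -0.65. Cyp4a14 missed the fold threshold at -0.99 without FF liver array 2 and at -0.9999 without Dhep liver array 3. Other genes that fell were the class I MHC gene H2-Bl (-2.17), the ion channel gene Asic5 (-2.06), the lipid transporter Abca3 (-1.37), Prxl2b (-1.36) and Dct (-1.34). Nlrp12 was above the floor in FF liver alone and was at least 8.21-fold lower in Dhep liver. Cptp was at least 3.66-fold lower by 1 probe, while its other probe differed by 0.04. The called probes of Abca3, Prxl2b and Cptp were low in Dhep liver alone. Markers of stellate cells (median -0.01) and hepatocyte identity genes (-0.02) showed no called member among 22 and 28, and no marker of 25 for sinusoidal endothelium was called (median 0.04, adjusted p = 0.138 with an estimated correlation, and -0.05 after median scaling).

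By limma's camera with the preset correlation, 16 of 41 lists shifted in liver, 13 up and 3 down, and 9 of these held with an estimated correlation. All counts of list members were the same adjusted over the list alone as over all probes, in this and the other 4 contrasts. With median scaling, 82 probes were higher and 30 lower, against 115 and 21. That scaling moved the medians to 0.15 for interferon-stimulated genes, 0.09 for NF-κB targets, 0.08 for acute phase genes and -0.41 for PPARα targets. Each genotype was represented by 1 mouse in this comparison, so the p-values do not separate genotype from the individual.

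**Figure D1:**
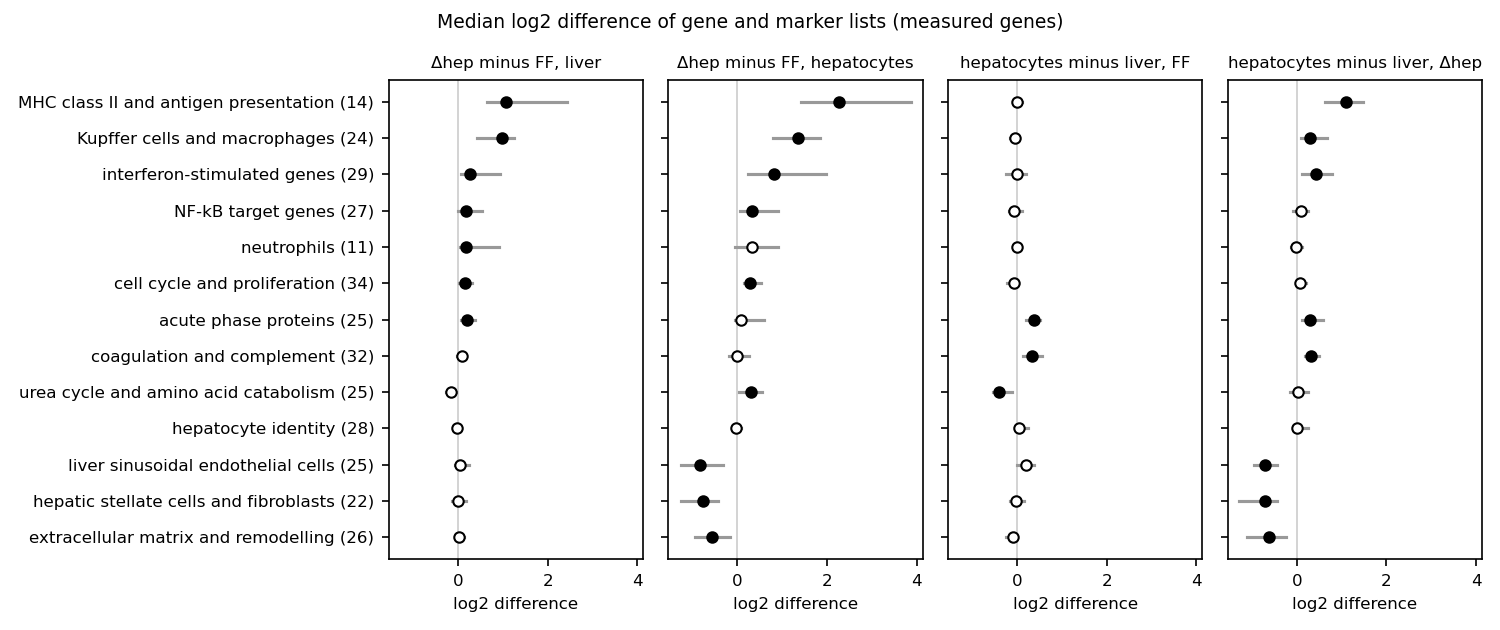
Median log2 difference of 13 gene lists in 4 comparisons: points are medians over list members, bars run from the 25th to the 75th percentile, and filled points have an adjusted p under 0.05 with an estimated correlation. MHC class II and antigen presentation genes had medians of 1.08 and 2.26 for genotype in liver and hepatocytes, and endothelial markers had medians of 0.04 (-0.05 after median scaling) and -0.83.

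The same genotype contrast was made in isolated hepatocytes, where immune genes were again higher. Cd74 was 36.3-fold higher in Dhep hepatocytes (5.18 ± 0.05, SE, n = 3 arrays per group, limma adjusted p = 4.62e-27) and H2-Ab1 was 22.3-fold higher (4.48 ± 0.06). Gbp2b, an interferon-inducible guanylate-binding protein, was 11.8-fold higher (3.56 ± 0.06). Cd163, a haemoglobin scavenger receptor of macrophages, was 4.15-fold lower (-2.05 ± 0.06), and Bgn, the matrix proteoglycan biglycan, was 2.82-fold lower (-1.50 ± 0.06). In all, 278 probes were higher and 283 lower, for 197 and 194 named genes, and 34 and 73 of the probes carried no gene symbol. Of the 283 lower probes, 88 were ones on which FF hepatocytes alone stood above the other 3 RNA samples, and 30 ones on which Dhep hepatocytes alone stood below.

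Of 14 MHC class II and antigen presentation genes, 11 rose and 0 fell in Dhep hepatocytes, with a median of 2.26 (adjusted p = 0.000864 with an estimated correlation). Examples were H2-Eb1 (4.18), H2-DMa (3.91) and H2-Aa (3.79). Of 29 interferon-stimulated genes, 13 rose and 0 fell, with a median of 0.80 (0.00192). Gbp3 rose by 3.10, Igtp by 2.94, Ifi47 by 2.82 and Gbp2 by 2.79, while a second Gbp2 probe stood at 0.56. Gvin1 (3.95) and Tgtp1 (at least 3.41, its FF mean lying under the floor), further interferon-inducible GTPases, also rose. Of 24 Kupffer cell and macrophage markers, 15 rose and 1 fell, with a median of 1.34 (0.000596). Mpeg1 rose by 2.44 (0.82 on its other probe), Adgre1, which encodes F4/80, by 2.03 and Marco by 2.02, while Cd163 fell.

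NF-κB target genes included 7 risers and 0 fallers among 27 (median 0.31, adjusted p = 0.00579 with an estimated correlation). Lcn2 rose by 3.07, the adhesion molecule Vcam1 by 2.49 (0.25 on the lowest of its 3 probes), the transcription factor Irf1 by 1.98 (0.58 on the lowest of its 5 probes) and Tnfaip2 by 1.41, on a probe low in FF hepatocytes alone. Of 34 cell cycle genes, 4 rose and 0 fell (median 0.28, 0.00351). They were Ccnd1, the cyclin of G1 (1.28, and 0.85 on the lowest of its 3 probes), Cdc20 (1.198, and 0.37 on another probe), the replication helicase subunit Mcm6 (1.08) and the cell cycle inhibitor Cdkn1a (1.13, and 0.31 on another probe). Mcm6 stood at 0.997, just under the threshold, with cyclic loess.

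Metabolic lists shifted by small amounts in Dhep hepatocytes. Gluconeogenesis and glycolysis had a median of 0.35 (adjusted p = 0.00883 with an estimated correlation) and 1 called member of 20, the glycogen synthase Gys2 (1.02, and 0.98 with cyclic loess). Urea cycle and amino acid catabolism had a median of 0.30 (0.0445) with 0 called of 25. Periportal genes had a median of 0.22 (0.0466) with 1 called of 17, Sult5a1 (1.75). Proteasome genes had a median of 0.27 (0.0236) with 0 called of 26, Psme1 standing at 0.88, or 1.196 with median scaling. Cytosolic ribosomal proteins had a median of -0.31 (0.0302) with 0 called of 22, Rpl30 standing at -0.95. The mitochondrial respiratory chain had a median of -0.21 (0.0236) that turned to 0.05 with median scaling, and 1 called member of 32, Uqcrq (-1.34, and -0.87 with that scaling). The Uqcrq probe, which has no curated mRNA accession, was high in FF hepatocytes alone (8.67, against 7.33 in Dhep hepatocytes and 7.47 in liver of either genotype). The hepatocyte identity list had no called member of 28 and a median of -0.03.

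Endothelial, stellate and mesothelial markers were lower in Dhep hepatocytes. Of 25 markers of liver sinusoidal endothelial cells, 11 fell and 0 rose, with a median of -0.83 (adjusted p = 0.00228 with an estimated correlation). Examples were Ramp2 (-1.63), Gpr182 (-1.51), the VEGF receptor Flt1 (-1.46) and the scavenger receptor Stab1 (-1.32, and -0.64 on the mildest of its 3 probes). Of 22 stellate cell and fibroblast markers, 8 fell and 0 rose, with a median of -0.76 (0.00107). They included smooth muscle actin Acta2 (-1.58, and -0.20 on its mildest probe), Bgn, Sparc (-1.35) and Colec11 (-1.31). Among 26 extracellular matrix genes, 5 fell and 1 rose, with a median of -0.56 (0.00228). Col4a1, a basement membrane collagen, fell by 1.10, and Fn1, fibronectin, rose by 1.30 (0.80 on its other probe). Of 9 mesothelial markers, 2 fell, Cav1 (-1.19) and Igfbp5 (-1.16, and -0.68 on the mildest of its 3 probes), with a median of -0.34 (0.0373). With median scaling these single calls were lost for Flt1 (-0.96), Stab1 (-0.86), Sparc (-0.86), Colec11 (-0.80), Col4a1 (-0.62), Cav1 (-0.89) and Igfbp5 (-0.72).

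The largest negative differences lay outside these lists, and most came with a high level in FF hepatocytes. Erich5 was 7.93-fold lower in Dhep than in FF hepatocytes (-2.99 ± 0.06), followed by Zxda (-2.64), Prf1 (-2.63), Fam126b (-2.20, and -0.58 on the mildest of its 3 probes), Rhbdl2 (-2.19) and Serpina4-ps1 (-2.07). On these 6 probes Dhep hepatocytes were nearer to liver than FF hepatocytes were, as with Erich5, at 12.27 in FF and 9.29 in Dhep hepatocytes against 9.26 in FF and 9.87 in Dhep liver. Nat8 (-2.53) and 2900060B14Rik (-2.50) were also lower in Dhep hepatocytes than in liver, and Nat8 fell in liver as well. Of the probes called, 77 were higher in both preparations, against 1.40 if the calls were independent, and 5 were lower in both, against 0.26. Over all probes the genotype differences in the 2 preparations correlated at a Pearson r of 0.29 and a Spearman r of 0.07, and 373 of the 561 probes called in hepatocytes had the same sign in liver. None was called in opposite directions by limma. With the preset correlation 18 lists shifted, 12 up and 6 down, and 15 held with an estimated correlation. The 3 lost were neutrophil markers (median 0.32, adjusted p = 0.0644 with an estimated correlation), acute phase genes (0.07, 0.207) and the IKK pathway list. With median scaling 914 probes were higher and 73 lower, and the median of all probes moved by 0.17, so the balance of rises and falls in this comparison rested on the scaling. List medians with that scaling were -0.52 for endothelium, -0.42 for stellate cells, -0.35 for extracellular matrix, -0.01 for ribosomal proteins, 0.60 for NF-κB targets, 0.57 for the cell cycle, 0.64 for gluconeogenesis and glycolysis, 0.50 for the urea cycle, 0.48 for periportal genes and 0.56 for the proteasome.

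**Figure D2:**
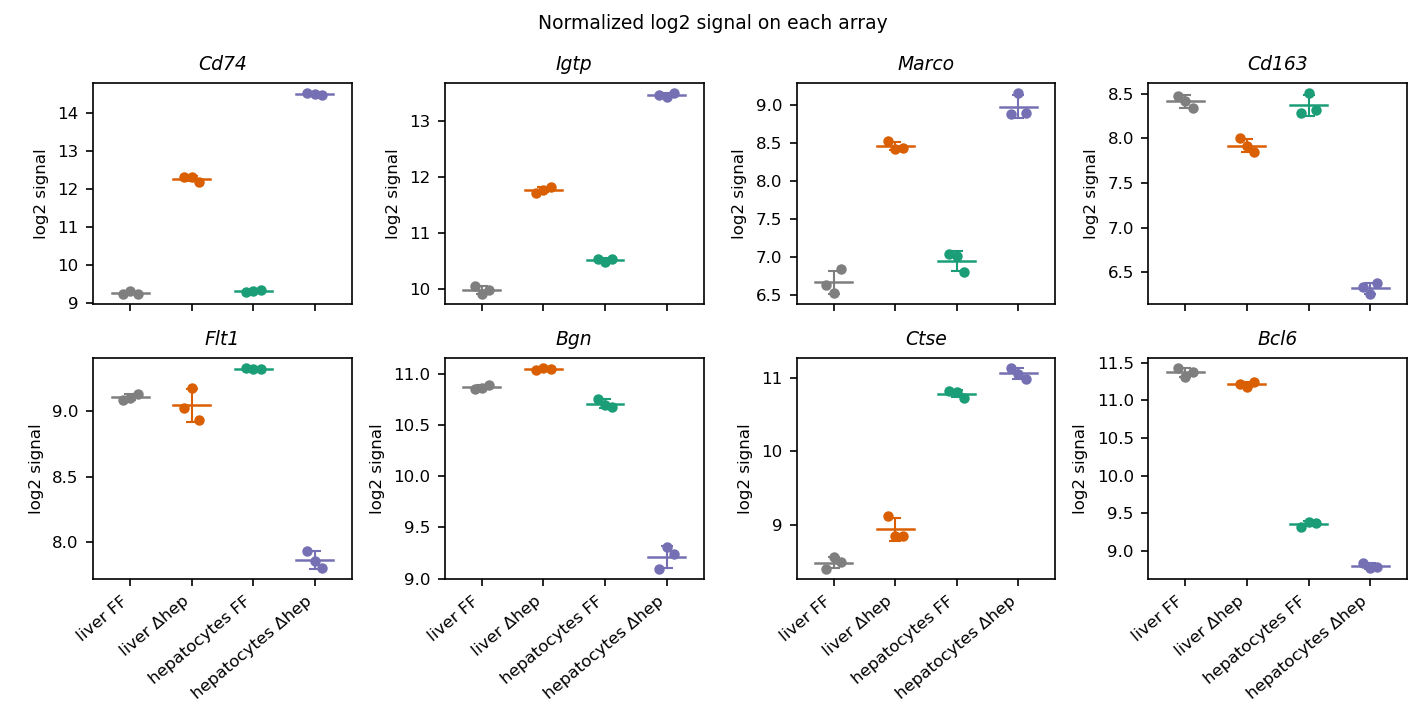
Normalized log2 signal of 8 genes in the 4 groups: points are the 3 arrays of a group, lines the means and bars the SD. Cd74 means were 9.27 in FF liver and 9.32 in FF hepatocytes but 12.28 and 14.50 in Dhep, while Bgn means were 9.21 in Dhep hepatocytes and 10.71 to 11.05 in the other groups.

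The next comparison asked how isolated hepatocytes differed from liver tissue in FF. Ctse, the aspartic protease cathepsin E, was 4.92-fold higher in hepatocytes (2.30 ± 0.07, SE, n = 3 arrays per group, limma adjusted p = 5.22e-18). Alas1, the rate-limiting enzyme of hepatic heme synthesis, was 3.91-fold higher (1.97 ± 0.06), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 5.46-fold higher (2.45 ± 0.05). Bcl6, a transcriptional repressor, was 4.04-fold lower (-2.01 ± 0.05). In all, 286 probes were higher and 44 lower, of which 103 and 5 carried no gene symbol (4778 and 6141 probes without the fold threshold), and 88 of the higher probes were those on which FF hepatocytes alone stood apart.

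The named changes spanned several functions. Metallothionein Mt1 rose by 2.19, the cytokine signalling inhibitors Socs2 and Cish by 2.42 and 2.10, the lipid transporter Mfsd2a by 2.48 and Tuft1 by 1.49 (0.39 on another probe). Zbtb20 rose by 2.50 on 1 probe and stood at 0.42 on another. Tubb2b, a β-tubulin, fell by 1.78 on 1 probe, with 0.06 on another, and Sox9, a transcription factor of bile duct cells, fell by 1.18 (-0.32 on its other probe). Immediate early and stress genes went both ways, 2 of 24 higher and 2 lower, with a median of -0.04 (camera adjusted p = 0.953). Gadd45g (2.51) and Ccn2 (1.68, high in FF hepatocytes alone) rose, and Egr1 (-2.22) and Junb (-1.12) fell. Of 18 circadian clock genes, 2 rose, Usp2 (1.92, and 0.08 on another probe) and Ciart (1.45, and 0.68 on the lowest of its 3 probes), and 1 fell, Arntl, which encodes BMAL1 (-1.09, and -0.99 with cyclic loess). The clock list did not shift as a whole (camera adjusted p = 0.521).

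Secreted hepatocyte products had higher medians in FF hepatocytes than in FF liver. Coagulation and complement genes had a median of 0.33 (adjusted p = 0.0118 with an estimated correlation) with 0 called of 32, F10 and Hc standing at 0.89 and 0.76. Acute phase genes had a median of 0.38 (0.0189) with 1 called of 25, Mt1. With median scaling these 2 medians were 0.04 and 0.10, or 0.19 and 0.25 relative to the shift of all probes. Growth factors and receptors had a median of 0.28 (0.0118), -0.02 with median scaling or 0.13 relative to that scaling's shift, and 2 of 28 rose. These were Il6ra (1.204, and 0.05 on the lowest of its 3 probes) and Inhbe (1.18), at 0.74 and 0.75 with median scaling. Urea cycle and amino acid catabolism fell, with a median of -0.41 (0.0227) and 2 called of 25, the histidine-degrading enzyme Hal (-1.19) and the cysteine-forming enzyme Cth (-1.23). Nrf2 targets and glutathione genes had a median of -0.30 (0.0227) with 0 called of 22, Gsta1 standing at -0.90, or -1.40 with median scaling, and proteasome genes -0.30 (0.0118) with 0 called of 26. With median scaling the urea cycle, Nrf2 and proteasome medians were -0.76, -0.53 and -0.73. Bile acid genes had a median of 0.20 (adjusted p = 0.0643 with an estimated correlation), which turned to -0.08 with median scaling, and Cyp7a1 was the 1 called of 20. Of 20 genes of gluconeogenesis and glycolysis, 1 rose, the glucose-6-phosphatase G6pc (1.33, and 0.95 with median scaling).

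No list of markers of other liver cells shifted in FF hepatocytes with an estimated correlation. Medians were -0.05 for Kupffer cells and macrophages, -0.02 for stellate cells and 0.19 for sinusoidal endothelium (adjusted p = 0.0643 with an estimated correlation, and -0.18 with median scaling). The MHC class II median was -0.01 and that of hepatocyte identity genes 0.04. With median scaling the medians were -0.44 for macrophages, -0.37 for stellate cells and -0.28 for MHC class II, so how near these lists stayed to their liver level rested on the scaling. With the preset correlation 9 lists shifted, 6 up and 3 down, and 6 held with an estimated correlation. The higher total rested on the scaling: with median scaling 115 probes were higher and 551 lower, and the median of all probes moved by -0.15.

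In Dhep mice, isolated hepatocytes differed from liver in marker and immune genes, among others. Cd74 was 4.67-fold higher in Dhep hepatocytes than in Dhep liver (2.22 ± 0.05, SE, n = 3 arrays per group, limma adjusted p = 2.03e-19). Hamp2, a paralogue of the iron hormone hepcidin, was 3.86-fold lower (-1.95 ± 0.06), and Bgn was 3.58-fold lower (-1.84 ± 0.06). In all, 113 probes were higher and 108 lower, for 86 and 83 named genes.

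Of 14 MHC class II and antigen presentation genes, 7 rose and 0 fell (median 1.10, adjusted p = 0.00158 with an estimated correlation). Of 29 interferon-stimulated genes, 5 rose and 0 fell (median 0.43, 0.00395), among them Gbp3 (1.86), Igtp (1.69) and Gbp2 (1.68, and 0.34 on its other probe). Kupffer cell and macrophage markers had a median of 0.30 (0.00898), with Mpeg1 (1.15, and 0.48 on its other probe) among 2 of 24 that rose and Cd163 (-1.60) the 1 that fell. Of 25 endothelial markers, 4 fell and 0 rose (median -0.71, 0.00158), including Plvap (-1.40), Ramp2 (-1.36), Flt1 (-1.18) and Eng (-1.17). With median scaling Flt1 and Eng missed the threshold, each at -0.99. Of 22 stellate cell and fibroblast markers, 9 fell and 0 rose (median -0.70, 0.000981), such as Acta2 (-1.52, and -0.15 on its mildest probe), Reln (-1.50) and Colec11 (-1.42). Of 26 extracellular matrix genes, 10 fell and 0 rose (median -0.62, 0.00112), including Col14a1 (-1.31, and -0.68 on its other probe) and Col4a1 (-1.29). Of 28 cytoskeleton genes, 5 fell and 0 rose (median -0.15, 0.0252, and -0.08 with median scaling).

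Coagulation and complement genes had a median of 0.31 in Dhep hepatocytes against Dhep liver (adjusted p = 0.00557 with an estimated correlation) with 0 called of 32. Acute phase genes had a median of 0.30 (0.0179), 3 rising and 1 falling of 25. Mt1 (1.22), the lipopolysaccharide-binding protein Lbp (1.07) and Lcn2 (1.68) rose, and Socs3 (-1.31) fell, on a probe high in Dhep liver alone. Bile acid genes had a median of 0.30 (0.00898) with 0 called of 20. Of 17 periportal genes, 3 rose (median 0.31, 0.0175), among them G6pc (1.18), Sult5a1 (1.12, and 0.71 on its other probe) and Ctsc (1.02). Ctsc stood at 0.99 without Dhep liver array 1 or Dhep hepatocyte array 2, and at 0.98 with cyclic loess. Ribosomal protein genes had a median of -0.32 (0.00898) and the respiratory chain -0.24 (0.00557, and -0.13 with median scaling), with 0 called of 22 and 32. With the preset correlation 17 lists shifted, 8 up and 9 down, and 15 held with an estimated correlation. The 2 lost were T and NK cell markers (median -0.19, adjusted p = 0.0517 with an estimated correlation) and erythroid markers (-0.11, 0.101). With median scaling 168 probes were higher and 72 lower.

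Some isolation changes were shared by both genotypes. Ctse was 4.35-fold higher (2.12 ± 0.07) and Alas1 2.94-fold higher (1.56 ± 0.06) in Dhep hepatocytes as well, and Bcl6 was 5.33-fold lower (-2.41 ± 0.05). Tuft1 (1.96, and 0.16 on its other probe), Cish (1.42), Mfsd2a (1.14), Zbtb20 (1.08, and -0.01 on another probe) and Socs2 (1.04, and just under 1 with cyclic loess) rose again, and Sox9 (-1.48, and -0.40 on its other probe) and Tubb2b (-1.18, and 0.14 on another probe) fell again. In all, 21 probes were called higher in both genotypes, against 1.41 if the calls were independent, 4 were lower in both, against 0.21, and 1 was called in opposite directions. Over all probes the isolation differences correlated at a Pearson r of 0.18 and a Spearman r of 0.14.

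The genotype difference between the hepatocyte RNA samples differed from that between the liver RNA samples for 579 probes by the interaction test in limma. Of these, 171 had a higher and 408 a lower value in hepatocytes (5467 and 4857 without the fold threshold). Each group was 1 RNA sample of 1 mouse, so the interaction also holds differences between mice, and the test cannot separate these from the preparation. Gm12250, an interferon-inducible GTPase, had a genotype difference of 0.45 in liver and 3.36 in hepatocytes (interaction 2.91). Tgtp1 had 1.12 and at least 3.41 (interaction at least 2.28). Endothelial markers had an interaction median of -0.996 (adjusted p = 0.0023 with an estimated correlation), with 0 called higher and 12 lower of 25. Stellate markers had -0.69 (0.00198) with 10 lower of 22, and MHC class II and antigen presentation genes 1.24 (0.0045) with 9 higher of 14. With median scaling these interaction medians were -0.47, -0.33 and 1.74. Prf1, the pore-forming protein of cytotoxic lymphocytes, had 0.36 in liver and -2.63 in hepatocytes. Hba-a1, an α-globin gene, had 1.67 and -0.99. With median scaling 1900 probes were higher and 112 lower, where the median of all probes moved by 0.23, and with cyclic loess 115 were higher and 478 lower.

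Across the 4 RNA means limma called 0 probes for isolation and 0 for genotype. The error of that fit is the interaction. It holds differences between mice together with any dependence of the genotype difference on the preparation. Probes with a large interaction thus had a large error, so the 0 calls do not measure the spread between mice alone. At an unadjusted p under 0.05 there were 1691 probes (7.40%) for isolation and 1126 (4.93%) for genotype, and the smallest adjusted p were 0.664 and 0.901. Leaving out single arrays moved these to between 0.631 and 0.650 for isolation and between 0.655 and 0.804 for genotype. With all 12 arrays and the RNA sample as a random block (duplicateCorrelation, consensus correlation 0.566), 91 probes were called for isolation, 75 higher and 16 lower. The same fit called 169 for genotype, 149 higher and 20 lower. It applies that consensus correlation to all probes and draws its error from 12 arrays, although there were 4 RNA samples. Repeat arrays thus count in part as separate samples, and these calls do not fully allow for differences between mice.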

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

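The splits of the arrays, the tests of macrophage number, single mice, carry-over and normalization, and the test on probes without a curated mRNA accession were chosen after the results were seen.

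For 70 of the 119 named probes, 31 higher and 39 lower, the genotype difference in hepatocytes differed from that in liver by the interaction test in limma. Over all kept probes it did so for 579 of 22859. The named probes were chosen in part for large genotype and interaction differences, so their larger share follows from the choice. The values here are the log2 genotype difference in hepatocytes minus that in liver, with the 3 arrays of each group, and they also hold differences between mice. Among MHC class II genes they were 2.17 and 2.63 for a pair of Cd74 probes, 1.44 for H2-Ab1, 1.24 for H2-Aa, 1.24 for H2-Eb1, 2.08 and 1.82 for a pair of H2-DMa probes and 1.85 for H2-DMb1. Interferon-inducible genes gave 2.91 for Gm12250, 2.24 for Gbp2b, 2.07 for Gbp3, 1.95 for Gvin1, 1.72 for Ifi47, 1.69 for Gbp2, 1.39 for Irf1 and 1.16 for Igtp. Further inflammatory genes gave 1.58 for Vcam1, 1.18 for Tnfaip2, 1.18 for Lcn2 and 1.08 for Mpeg1. Higher values also came from H2-Bl (2.71), Egr1 (1.73), Asic5 (1.46), Hal (1.46), Fn1 (1.37), Sult5a1 (1.35), Prxl2b (1.32) and Abca3 (1.21).

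Lower values rested in part on the scaling. Over all probes 408 had a lower interaction call, against 112 with median scaling, which kept 283 of the 579 calls. For most of the named probes the interaction was not compared between scalings. Lower values came from endothelial markers, namely Ramp2 (-1.97), Gpr182 (-1.79), Flt1 (-1.39), Eng (-1.36), Plvap (-1.32), Stab1 (-1.18) and Lyve1 (-1.01). Stellate and matrix genes gave -1.82 for Acta2, -1.68 for Bgn, -1.50 for Colec11, -1.40 for Col4a1, -1.37 for Sparc, -1.15 for Reln and -1.05 for Col14a1. The macrophage marker Cd163 gave -1.56, the blood gene Hba-a1 -2.67 and the iron gene Hamp2 -2.23. Signalling and stress genes gave -2.03 for Gadd45g, -1.65 for Ccn2, -1.54 for Il6ra, -1.39 for Socs2, -1.11 for Socs3, -1.08 for Ccl5 and -1.02 for Inhbe. Clock genes gave -1.58 for Ciart and -1.53 for Usp2. The remaining ones were Erich5 (-3.59), Zxda (-3.12), Prf1 (-2.99), Rhbdl2 (-2.53), Fam126b (-1.95), Serpina4-ps1 (-1.81), 2900060B14Rik (-1.79), Cyp7a1 (-1.52), Zbtb20 (-1.42), Mfsd2a (-1.34), Uqcrq (-1.34) and Rpl30 (-1.03). For 4 of the 70 probes the fitted value used a group mean under the floor and is no measured size: 2.34 for Tgtp1, at least 2.28 against the floor in FF hepatocytes, 3.32 for Nlrp12, at the floor in 3 groups, 1.98 for Cptp, at least 1.90 against the floor in Dhep liver, and -2.89 for Cox6b2, -2.81 or lower against the floor in FF liver. Other kept probes of these genes gave as little as 0.03 for Cptp, 0.20 for Vcam1, 0.36 for Gbp2, 0.41 for Irf1, 0.58 for Mpeg1, 0.74 for Tnfaip2, 0.97 for Fn1, -0.09 for Usp2, -0.17 for Il6ra, -0.18 for Acta2, -0.28 for Fam126b, -0.43 for Zbtb20, -0.47 for Stab1, -0.47 for Col14a1, -0.59 for Rpl30 and -0.73 for Ciart.

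Of the 41 lists, 10 differed between preparations with an estimated correlation. Interaction medians were 1.24 for MHC class II, 0.54 for interferon-stimulated genes, 0.46 for Kupffer cells and macrophages, 0.36 for urea cycle and amino acid catabolism, 0.35 for the proteasome, 0.34 for gluconeogenesis and glycolysis and 0.17 for the cell cycle. They were -0.996 for sinusoidal endothelium, -0.69 for stellate cells and -0.52 for extracellular matrix. With median scaling they were 1.08 for interferon-stimulated genes, 1.04 for macrophages, 0.85 for the urea cycle, 0.80 for the proteasome, 0.83 for gluconeogenesis, 0.49 for the cell cycle, -0.47 for endothelium, -0.33 for stellate cells and -0.31 for extracellular matrix. Of 100 splits of the arrays into groups of the same sizes, 1, the real one, gave as many interaction calls, with 579 calls against at most 397. The arrays of a group repeat 1 RNA sample, so other splits mix RNA samples, which widens the spread within groups. The share was thus largely fixed by the design, and no conclusion about chance is drawn from it. It says nothing about chance in the choice of mice or RNA samples. For the other 4 contrasts the 10 splits are too few for a share under 0.05. In each, 1 split, the real one, gave as many calls, with 136, 561, 330 and 221 calls against at most 0 in the others.

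MHC class II and interferon-stimulated genes were higher in RNA labelled Dhep in both preparations. Normalization was argued against for MHC class II, whose liver median stayed between 0.91 and 1.17 over 6 background and normalization settings, and for the direction though not the size of the interferon list, whose lowest liver median was 0.15 (bootstrap interval 0.02 to 0.83) with median scaling. A larger number of macrophages of unchanged content may account for part of it. In hepatocyte RNA the median of the MHC class II and antigen presentation list exceeded the macrophage median by 0.92. The bootstrap interval of -0.07 to 2.69 leaves this open. That list also holds class I genes, so it does not test class II genes alone. Among them, log2 means in FF and Dhep hepatocytes were 14.83 and 14.95 for B2m, 12.81 and 14.10 for H2-D1, and 12.92 and 13.60 for H2-K1. The brightest macrophage markers went from log2 means of 12.09 in FF to 13.10 in Dhep hepatocytes for Slc40a1, 10.33 to 12.77 for Mpeg1 and 10.63 to 11.27 for Hpgd, and 2 of the 24 markers also stand in other lists. A difference between single mice cannot be told apart from genotype, since each group was 1 mouse. The fit over 4 RNA means called 0 of 42 list members (smallest adjusted p 0.901), but it called 0 of all 22859 probes, so it could not decide this. At an unadjusted p under 0.05 in that fit there were 23 of the 42, against 4.93% of all probes, in lists singled out by the same data. The genotype itself stays open as an explanation.

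Endothelial and stellate markers had median isolation differences of 0.19 and -0.02 in FF and were lower in Dhep hepatocyte RNA. If carry-over of all non-parenchymal cells into the FF preparation were the sole difference, every such list would have a lower isolation difference in Dhep. Dhep minus FF, the medians were 0.46 (0.23 to 0.72) for macrophages, -0.996 (-1.199 to -0.64) for endothelium and -0.69 (-1.14 to -0.41) for stellate cells. The macrophage value argues against that for these RNA samples. Macrophage markers also differed by genotype, so carry-over of endothelial and stellate cells into the FF preparation stays open. Normalization was argued against for the fall in Dhep, where the endothelial median lay between -0.84 and -0.61 over 6 settings, but stays open for the level in FF, where the stellate median was -0.37 with median scaling. The brightest endothelial marker, Clec4g, had a mean of 12.21 in FF and 11.42 in Dhep hepatocytes, and the brightest stellate marker, Dcn, 12.43 and 11.39, while 11 of the 22 stellate markers stand in other lists and 0 of the 25 endothelial ones. A removal of endothelial and stellate cells that differed between the preparations, together with a change in macrophages, remains open and untested, as does genotype.

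On some probes 1 RNA sample stood apart from the other 3: 2 probes for FF liver, 8 for Dhep liver, 93 for FF hepatocytes and 43 for Dhep hepatocytes. Faults of single arrays were argued against, since 100% of the probes of each RNA sample were at least 0.5 log2 apart from all other groups on each of its 3 arrays. For Dhep hepatocytes, 2 of 38 genes lay near another such gene (percentile 9.54 of random sets). This argues only against inherited chromosome segments that hold many of these genes. In simulated sets with several genes from the same segment the test found 78.6%, so a segment with few genes could be missed. Pairs of genes whose symbols share the first 3 letters were not counted. Segments stay open for FF hepatocytes, where 13 of 54 lay at percentile 87.4, under the 95th percentile of 15 by too little to decide. They also stay open for FF and Dhep liver, with 0 of 1 and 0 of 5 genes. Of 88 probes higher in FF hepatocytes alone, 76.1% had no curated mRNA accession against 18.9% of probes of like signal. The ratio was 4.04 (3.54 to 4.51), as unspliced or non-coding transcripts would give. Of 30 genes with such a probe lacking the accession, 23 had other probes with one. Those other probes had a median isolation difference in FF of -0.036 (-0.14 to 0.19), which argues against higher levels of these 23 whole genes. Genes raised on a probe with the accession were not in that test. They include Ccn2, which rose on its 2 kept probes, so the argument does not cover them. Nuclear-retained transcripts lay at percentile 92.5 of random lists (median 0.05, 21 genes), which leaves nuclear RNA open, and genomic DNA was not tested, although the labels state DNase I treatment.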

How the results depend on the processing

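An offset of 16 in the background correction was chosen after seeing the data. With it 213 probes were called for genotype in liver, 1050 for genotype in hepatocytes, 603 for isolation in FF, 360 for isolation in Dhep and 1116 for the interaction, where 136, 561, 330, 221 and 579 were called as reported, since a smaller offset widens differences of dim probes by construction. With no fold threshold these counts were 6351, 12312, 10919, 9565 and 10324, since that step removes a criterion. With limma's treat against a fold of 1.5, a criterion lower than the fold of 2 by construction, they were 208, 1172, 705, 501 and 944, and isolation in Dhep then split into 206 higher and 295 lower. Median scaling gave 987 for genotype in hepatocytes, 666 for isolation in FF and 2012 for the interaction, and the cause was not tested. These contrasts all use the FF hepatocyte arrays, whose raw 75th percentiles were 75.5 to 85.7, against 94.7 to 119 on the other arrays. Median scaling, unlike quantile normalization, leaves such a difference in distribution in place. It kept 103 of the 136 calls for genotype in liver, 351 of 561, 159 of 330, 185 of 221 and 283 of 579, with 0 called in the opposite direction. Cyclic loess kept 134, 504, 301, 207 and 517 of them. With all arrays and the RNA sample as a random block, 91 probes were called for isolation and 169 for genotype, against 0 and 0 over the RNA means. In the random block fit repeat arrays still count in part as separate samples. Every other alternative stayed within 1.5 times the reported count for the array contrasts. With the replicate number as a block, as if arrays were paired, the counts were 136, 561, 330, 221 and 579. That number did not pair the arrays: for 18 pairs of arrays with the same number, r of their deviations from the group mean was -0.05 to 0.07. Leaving out each array gave 135 to 138, 559 to 575, 322 to 334, 213 to 225 and 577 to 596 calls, and 0 in either fit over RNA means. Gene values under the other alternatives numbered 1662, few of them interaction values. Of these, 1630 kept their call or stayed uncalled, 18 lost a call, 14 gained one and 0 called values reversed. Of 2050 list values, 1968, 50, 32 and 0 did so, a list counting as reversed only if called in opposite directions. Signs of uncalled values were not compared, and some list medians changed sign with median scaling, as given above. Leaving out single arrays, 2011 of 2016 gene values kept their call or stayed uncalled, 4 lost a call (Cyp4a14 and Ctsc) and 1 gained one (Cxcl10). A chip block was not run, since no chip is given in the sources used here, and a fit of only the groups compared gives no separate interaction. Signal near the floor of 66.7 limits dim genes, whose differences shrink toward 0 with the offset.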

Other observations

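None of the tests used here was chosen after the result was seen. Further genes differed between the livers. Socs2 (1.72) and Cish (1.47), feedback inhibitors of growth hormone and cytokine signalling, were higher in Dhep liver, as were Gadd45g (1.58), Cyp7a1 (1.24) and Hba-a1 (1.67), while the immediate early transcription factor Egr1 was lower (-1.17). Cox6b2, at the floor in FF liver, was at least 3.59-fold higher in Dhep liver. Of 24 immediate early and stress genes, 2 were called higher and 1 lower, and the list's call was lost (median 0.02, adjusted p = 0.0872 with an estimated correlation). Cholesterol synthesis had a median of 0.16 (adjusted p = 0.108 with an estimated correlation) and urea cycle and amino acid catabolism -0.16 (0.0755), each a call with the preset correlation that was lost. Coagulation and complement had a median of 0.09 (0.108), which turned to -0.12 with median scaling, and cytoskeleton genes 0.07 (0.0703), which turned to -0.01.

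In hepatocytes, the macrophage markers C1qb (1.97), Aif1 (1.64, and 0.67 on the lowest of its 3 probes) and C1qc (1.79) were higher in Dhep, as in liver, and so were the neutrophil markers Fpr2 (2.18) and S100a8 (1.31), the amyloid Saa3 (1.38) and the trefoil factor Tff3 (1.71). Hamp2 (-1.98) and Ccn2 (-1.96), a matricellular growth factor, were lower. In the FF isolation contrast, Irf1 (-1.29, and -0.29 on the mildest of its 5 probes) and Tnfaip2 (-1.04, and -0.54 on the mildest of its 3 probes, and low in FF hepatocytes alone) were lower in hepatocytes than in liver, and Erich5 (3.02), Serpina4-ps1 (2.73), Zxda (2.61) and Prf1 (2.48) were higher. In the Dhep isolation contrast H2-Bl (3.38) and Asic5 (1.85), both lower in Dhep liver than in FF liver, were higher in hepatocytes than in liver, as was Abca3 (1.67), which was low in Dhep liver alone. Cptp was at least 3.84-fold higher there by 1 probe. Ccl5 (-1.10, high in Dhep liver alone) and Hba-a1 (-2.34) were lower. The Alb probe was dim, at log2 means of 7.67 to 8.35, and was not called in any contrast.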
